A study of Homo sapiens with 6 samples.

How the data were processed

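Methylated RNA immunoprecipitation sequencing of Kasumi-1 cells was analysed from the tables the authors made from their reads. The 6 samples, 3 IP and 3 input libraries of the combined CoCl2 and echinomycin treatment, were grouped by their titles, and the labels describe the replicates as 3 biological replicates. Per the labels' protocols, poly(A) RNA was purified from total RNA, fragmented, split between input and an m6A antibody pulldown, and made into strand-marked paired-end libraries. Per the submitters' processing notes, fastp, HISAT2, HOMER and ChIPseeker were used, with no role or version given. The peak caller, the differential caller, the tool that estimated FPKM, the genome build and the annotation release are not given in the sources used here.

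In the peak list the authors gave each peak's fold enrichment as a linear ratio of IP over input, with a p-value per peak and log10 values of p and FDR, which were read as a score because some lie at minus infinity. In the differential list the authors gave a log2 fold change of enrichment, a p-value and a log10 FDR as a score for each peak. Each list gives 1 value per peak and no replicate values, and how the replicates were combined is not given in the sources used here. FPKM was deposited by the authors for each gene and input library, per the file headers, and the FPKM table had 6 other per-sample columns that were not used here. Ratios of low FPKM values between libraries showed no clear steps of whole reads, so the depth per library is unknown, and no interval that needs it was computed. No input column was identical to another.

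The fold change was taken as the combined treatment over CoCl2 from the order of the conditions in the table's name. This direction was checked against the peak list of the combined treatment. Of peaks in the authors' deposited table with a log2 fold change from -8 to -4, 3 of 49 (6.12%, exact 95% interval 1.28 to 16.9) overlapped a listed peak by at least 1 base, against 45.0% from -4 to -2 and 68 of 68 from 4 to 10. The labels themselves do not state the direction. The build is not named, and coordinates are printed as the tables give them. Among 23238 gene symbols present once in the reference gene table of GRCh38.p14, 99.9% overlapped the position that table gives for the gene, and that table was used only for this check. The peak list repeated 16 lines and the differential list 4 with the same gene and positions.

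A differential peak counted as changed at an authors' FDR under 0.05, with no fold limit, and a gene as expressed at a mean input FPKM of 1 or more. For gene lists, each gene was represented by its tested peak with the lowest authors' p. The median log2 fold change of a list, or the share of its expressed members with a listed peak, was placed as a percentile among 10000 random lists of the same size matched on 10 bins of mean input FPKM, and a list was called apart outside the central 95%, with at least 3 members needed. Random lists tied with the observed value were split evenly between both sides. Rank correlations of fold change with enrichment used peaks that overlapped the peak list and whose gene had an FPKM, and were repeated, after the data were seen, with peaks lacking an overlap ranked below all others. The authors' p of a list's genes were also adjusted by Benjamini-Hochberg over the list alone. Percentiles are descriptions, since genes are not replicates. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

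The 19 gene lists were fixed before the data were examined: m6A writers, erasers and readers, HIF pathway regulators, HIF target genes, glycolysis and glucose transport, p53 target genes, the DNA damage response, apoptosis, TNF and NF-kB signalling, the cell cycle and replication, the unfolded protein and integrated stress response, haematopoietic transcription factors, myeloid, lymphoid, and erythroid and megakaryocytic markers, chromatin regulators, ribosomal proteins, and nuclear genes of the mitochondrial respiratory chain. The rule for named genes was also fixed then. It took the 10 genes with the highest and the 10 with the lowest log2 fold change among changed peaks of expressed genes, up to 4 changed members per list by lowest authors' p, the 10 genes with the highest fold enrichment among genes with a mean input FPKM of 5 or more, the 10 genes with the highest mean input FPKM and up to 4 members per list by highest mean. All m6A writers, erasers and readers, and HIF1A, VEGFA, SLC2A1, LDHA, MYC, TNF, RUNX1 and RUNX1T1, could be named in any case. Some genes that the rule takes are not reported here.

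The percentile and interval functions were tested on simulated data. Among 10995 genes with a tested peak and an FPKM, 100 random lists of 14 genes were called apart 5 times without a shift, 13 times with a log2 shift of 0.5 and 52 times with a shift of 1. For 100 lists of 23 genes the calls were 3, 9 and 84. A list inside the random range can therefore hide a shift of 0.5. In 50 comparisons with a brute-force count, 0 overlaps differed.

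Alternatives were tried for the threshold, a fold limit, an expression filter, genes in place of peaks, the overlap with the peak list, the choice of peak per gene, the matching of random lists, and each input replicate left out. Matching on enrichment, an authors' FDR under 0.05 for the peak list, and leaving out exon peaks that carry another gene's exon were added after the data were seen. Terms deposited beside the peaks, from KEGG and GO, were tested after the data were seen, for terms of 20 to 1500 genes, by a one-sided Fisher's exact test against all annotated genes with a tested peak, with Benjamini-Hochberg adjustment per source and direction. A planned limma comparison of IP with input FPKM was not run, since the table used here gave input columns for these samples only. A comparison of peak change with expression change was not run, since no expression fold change was in the tables used here, and the DRACH motif was not searched, since no genome was used here.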

Results

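The data describe N6-methyladenosine (m6A), a methyl mark on messenger RNA, in Kasumi-1, an established human acute myeloid leukaemia line that carries the RUNX1-RUNX1T1 fusion. Cells were exposed for 24 hours to 100 uM CoCl2, a hypoxia mimic that stabilises the transcription factor HIF-1, together with 10 nM echinomycin, which blocks the binding of HIF-1 to DNA. In methylated RNA immunoprecipitation sequencing, fragmented poly(A) RNA is pulled down with an antibody against m6A (IP) and sequenced beside the RNA before the pulldown (input). The 6 libraries comprised 3 IP and 3 input libraries from 3 biological replicates of the combined treatment. The comparison of the combined treatment with CoCl2 addressed what echinomycin adds to the hypoxia mimic, and it was made by the authors. Libraries of CoCl2 alone were not analysed here. Each list gives 1 value per peak and no replicate values. How the replicates were combined is not given in the sources used here, and the depth of the libraries is unknown from FPKM values.

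After the combined treatment the strongest m6A peaks of well expressed genes lay at transcript ends. PARVG, a focal adhesion adaptor of blood cells, had a 3' UTR peak with a fold enrichment of 176 on chromosome 22 at 44207395 to 44207754. PLEKHA2, a phosphoinositide-binding adaptor, had a 5' UTR peak of 175 on chromosome 8 at 38901235 to 38901977, and ZNF175, a zinc finger protein, one of 162 on chromosome 19 at 51571283 to 51573316. The next 7 genes all had 5' UTR peaks: CAB39, a scaffold of the LKB1 kinase, at 138, CPSF7, a factor of mRNA 3' end cleavage, at 126, PURB, a nucleic acid-binding protein, at 119, GNB1, a G protein subunit, at 117, NUS1, an enzyme of dolichol synthesis, at 113, MFSD10 at 108 and FAM214A at 103. Input levels were 11.8 ± 0.923 FPKM (SD, n = 3) for PARVG and 16.9 ± 0.259 FPKM (SD, n = 3) for PLEKHA2. Fold enrichment is the authors' own value per peak, IP over input, and no error comes with it. The region label does not give how far a peak reaches, and the PURB peak covers 2818 exonic bases.

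The list held 42634 peaks in 17060 named genes, of which 6541 had exactly 1 peak. Peaks in 3' UTRs numbered 18128 (42.5%), peaks in other exons 14643 (34.3%) and peaks in 5' UTRs 9863 (23.1%). Median fold enrichment was 4.40 in 3' UTRs, 4.42 in 5' UTRs and 4.66 in other exons, against quartiles of 2.63 and 7.45 over all peaks. Of 12612 genes with a mean input FPKM of 1 or more, 10055 (79.7%) had a listed peak, from 65.2% in the lowest decile of expression to 86.9% in a middle one and 78.9% in the highest. The list was loose at its lower end, with 5357 peaks at an authors' FDR of 0.05 or more, and 7005 genes with a peak were under 1 FPKM or not in the FPKM table. Of the exon peaks, 2923 carried the exon of another gene than the gene they were assigned to.

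Regulatory genes nearly all carried a peak, while genes of mitochondrial respiration often did not. Every expressed member had a peak among p53 target genes (21 of 21), apoptosis genes (26 of 26), genes of the unfolded protein and integrated stress response (18 of 18), haematopoietic transcription factors (20 of 20) and chromatin regulators (24 of 24). In contrast, 10 of 24 nuclear genes of the mitochondrial respiratory chain (41.7%) and 23 of 36 ribosomal protein genes (63.9%) had a peak. The m6A machinery itself was marked, with a peak in 9 of 9 expressed writer genes. These build the methyltransferase complex, apart from METTL16, a separate methyltransferase. Peaks were also listed for 13 of 13 expressed readers, which bind m6A, and for ALKBH5, the 1 eraser above the expression limit. LDHA, the lactate-forming enzyme and a classical HIF-1 target, had no listed peak at 105 ± 3.03 FPKM (SD, n = 3).

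Against 10000 random lists of expressed genes matched on input FPKM, the respiratory chain lay at percentile 0 (random lists 66.7% to 95.8%) and ribosomal proteins at 1.96. The 5 complete lists named first had percentiles above the central 95%, with p53 target genes at percentile 99.4, apoptosis at 99.7, the stress response at 98.7, haematopoietic transcription factors at 98.9 and chromatin regulators at 99.3. The other 10 of 17 lists lay inside: m6A writers at 90.3, m6A readers at 96.8, HIF pathway regulators (9 of 10) at 64.9, HIF target genes (18 of 20) at 79.8, glycolysis and glucose transport (16 of 23) at 8.58, the DNA damage response (20 of 22) at 85.9, TNF and NF-kB signalling (17 of 19) at 68.3, the cell cycle (26 of 30) at 63.0, myeloid markers (11 of 11) at 97.3 and lymphoid markers (3 of 4) at 38.4. The erasers and the erythroid and megakaryocytic markers had 1 expressed member each, too few for a percentile. At a limit of 5 FPKM, p53 target genes (96.0), haematopoietic transcription factors (94.7), chromatin regulators (97.0) and ribosomal proteins (15.1) came inside, as did p53 target genes with peaks of fold enrichment of 2 or more (86.3). Without replicate 1, myeloid markers moved outside at 97.6. The random lists were not matched on transcript length, so whether length accounts for these differences between lists was not tested.

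**Figure D1:**
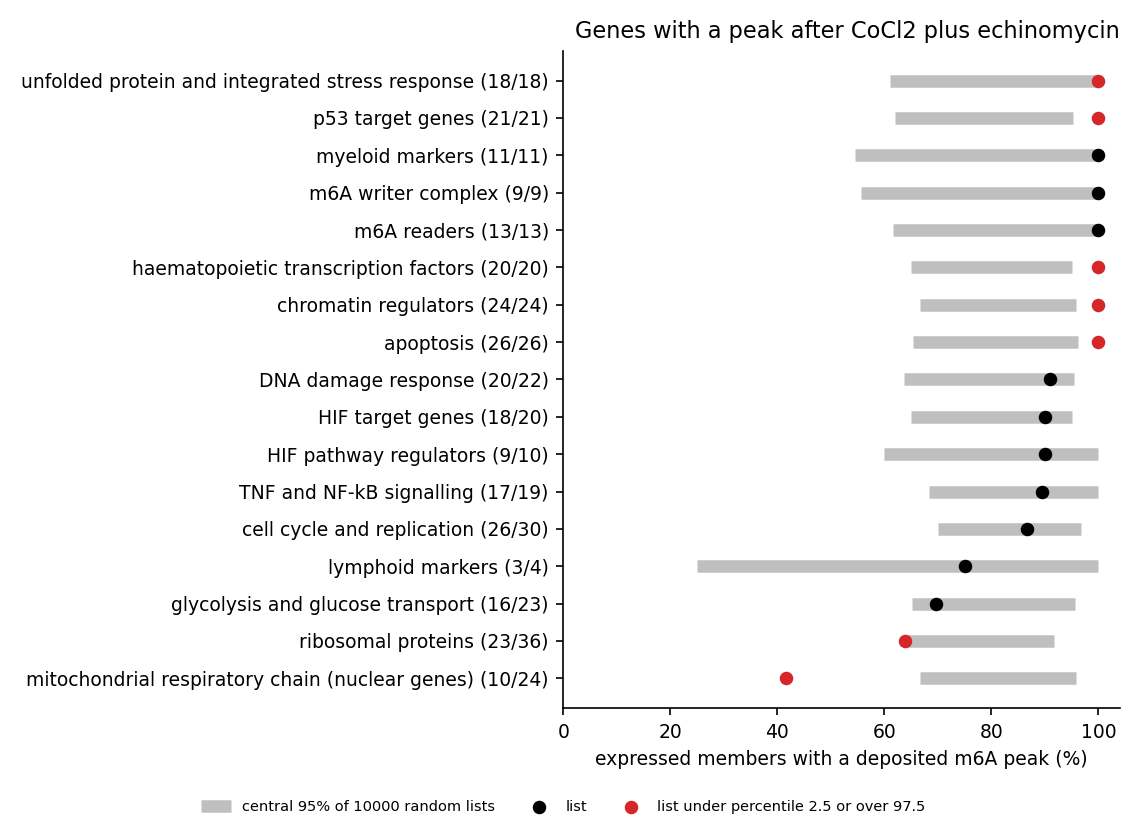
Percentage of the expressed members of each fixed gene list that had a deposited m6A peak after CoCl2 plus echinomycin (points, with members with a peak over expressed members in parentheses), and the central 95% of 10000 random lists matched on input FPKM (grey bars), in red where the list's percentile lies outside. The respiratory chain, at 41.7%, lies below its bar, which runs from 66.7% to 95.8%.

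With echinomycin added to CoCl2, more m6A peaks fell than rose, and the genes at both extremes were of mixed function. By the authors' deposited table, the highest fold change among expressed genes was a log2 of 9.90 in the 3' UTR of TRAPPC10, a subunit of a vesicle tethering complex, on chromosome 21 at 44103407 to 44104965 (log10 FDR -72.5). The same 3' UTR peak had the highest enrichment of the peak list, 295, in a gene of 3.63 ± 0.161 FPKM (SD, n = 3). That enrichment is of the combined treatment, which also enters the fold change, so it is no separate support. Leaving aside genes of uncertain identity and the unnamed locus AC093462, the next in the authors' deposited table were UPP1, a uridine phosphorylase, at 4.05, ACAT1, an enzyme of ketone body metabolism, at 4.01, ELOVL5, a fatty acid elongase, at 4.00 and ATOH7, a retinal transcription factor, at 3.97. Their log10 FDR was far weaker, at -2.76 for UPP1, -7.77 for ACAT1, -2.52 for ELOVL5 and -1.63 for ATOH7. UPP1 and ATOH7 were also close to the expression limit, at 1.02 and 1.22 FPKM. Without the genes taken up in the next paragraph, the lowest values of the authors' deposited table were -4.17 for PHLDA1, a pleckstrin homology domain protein (5' UTR, chromosome 12 at 76032942 to 76033122, log10 FDR -3.28), -3.86 for CEL, a bile salt-activated lipase with a related pseudogene that can share reads, -3.86 for EXOC2, a subunit of the exocyst, and -3.58 for XRCC3, a protein of recombination repair. The log10 FDR was -2.73 for CEL, -2.08 for EXOC2 and -1.77 for XRCC3.

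The genes left aside at the extremes were uncertain in identity. NOMO3 (4.98), XAGE1A (4.18), SLX1B (-3.60), F8A3 (-3.50) and GOLGA8H (-3.41) of the authors' deposited table have near-identical copies that can share reads. The peaks of AGAP2 (4.15), PITRM1 (-3.56) and CTU2 (-3.54) in the authors' deposited table carried an exon of AGAP2-AS1, PITRM1-AS1 and AC138028, and ZSCAN16-AS1 (4.94) is an antisense gene. The remaining names by the fixed rule were AC093462 at 4.03 and CEP43, a centriolar protein, at -3.52 in the authors' deposited table. AGAP2, ELOVL5, ATOH7, CTU2 and CEP43 had at least 1 other tested peak that changed the opposite way, and CTU2 turned to a higher value when its peak with the highest absolute fold change was taken.

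Of 19983 peaks in the authors' deposited table, 13773 (68.9%) passed the authors' FDR of 0.05, 4621 higher and 9152 lower after the combined treatment. The median log2 fold change in the authors' deposited table was 0.70 for higher peaks (quartiles 0.47 and 1.01), -0.70 for lower peaks (quartiles -0.99 and -0.48) and -0.43 for all peaks. A change of 2-fold or more was listed in the authors' deposited table for 1200 higher peaks (26.0%) and 2234 lower peaks (24.4%). Higher peaks lay in 3341 genes and lower peaks in 6323 genes of the authors' deposited table, and 1148 genes had both. In the 3' UTR, 70.1% of changed peaks of the authors' deposited table were lower (exact 95% interval 69.1 to 71.2), against 64.4% in other exons (62.7 to 66.2) and 60.6% in the 5' UTR (59.0 to 62.2). Intervals cover counting error only, the table gives no error per fold change, and it holds no replicate values. Whether the authors' FDR measures the spread between replicates is not given in the sources used here. Small changes of the authors' deposited table passed it, such as 0.0774 for CALR (log10 FDR -6.57) and -0.137 for RPL41 (-52.9). Passing the FDR thus does not show that a change repeated across the replicates. Counted as genes or at a 2-fold limit, the changed features of the authors' deposited table numbered 8516 and 3434, with 70.0% and 65.1% lower.

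Peaks on transcripts of the m6A machinery changed in both directions. Here and below, a gene called higher or lower, or said to rise or fall, is one whose peak of lowest p changed in m6A enrichment. Its expression was not compared with CoCl2 alone. Among writers in the authors' deposited table, 2 of 7 tested genes rose, WTAP, the targeting subunit of the methyltransferase complex, at 0.98 and ZC3H13, a zinc finger subunit, at 1.19. The other 5 writers of the authors' deposited table fell: RBM15 at -0.84, RBM15B at -0.72, VIRMA at -0.42, CBLL1 at -0.30 and METTL16, a separate methyltransferase, at -0.88. Peaks of both erasers, which remove m6A, fell in the authors' deposited table, ALKBH5 at -1.09 and FTO at -0.83. FTO lay under the expression limit, at 0.702 FPKM. Of 12 readers in the authors' deposited table, 4 fell, namely YTHDF1 (-0.45), YTHDF2 (-0.67), YTHDF3 (-0.66) and PRRC2A (-0.17). The 8 readers that rose in the authors' deposited table were YTHDC1 (0.50) and YTHDC2 (0.62), IGF2BP2 (0.79) and IGF2BP3 (0.67), ELAVL1 (0.79), HNRNPC (0.55), HNRNPA2B1 (0.31) and RBMX (0.33). The catalytic pair METTL3 and METTL14 had no peak among those the authors compared. The signs of ZC3H13, METTL16, YTHDF2 and RBMX turned with another choice among their peaks, and VIRMA, ALKBH5 and IGF2BP2 had peaks changed in both directions.

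Genes of the hypoxia pathway moved both ways. Among HIF pathway regulators in the authors' deposited table, 6 of 8 fell, with HIF1A, the oxygen-regulated subunit of HIF-1, at -0.89, and the coactivator gene CREBBP at -0.82, while EPAS1, which encodes HIF-2 alpha, rose by 0.72 (chosen after its value was seen). CITED2 (-0.41), VHL (-0.53) and EP300 (-0.40) also fell in the authors' deposited table, but their signs turned with another choice of peak, and the HIF1A peak carried another gene's exon. Of 16 HIF target genes in the authors' deposited table, 8 fell and 5 rose, the lower ones including DDIT4, an inhibitor of mTORC1, at -0.66, BHLHE40, a transcriptional repressor, at -0.53 and VEGFA, an angiogenic growth factor, at -0.43. KDM3A, a histone demethylase, was at -0.54 in the authors' deposited table and turned with another choice of peak. Of 12 genes of glycolysis and glucose transport in the authors' deposited table, 6 rose and 5 fell, with the glucose transporter gene SLC2A1 at 0.66 beside another of its peaks that fell. SLC2A3 (-0.42), HK2 (-0.38), PFKFB3 (-0.40) and SLC16A3 (0.40), by the authors' deposited table, turned with another choice of peak.

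Genes of death and inflammatory signalling were mostly lower at their peak of lowest p, though not beyond expression-matched random lists. With the mean of each gene's peaks, the medians of the authors' deposited table came to -0.081 for apoptosis (percentile 73.1), -0.15 for TNF and NF-kB signalling (42.6) and -0.0115 for the stress response (65.7). With the peak of highest absolute fold change they were -0.37 (percentile 55.3), -0.61 (7.99) and -0.28 (55.6) in the same order. The medians thus stayed below 0, but their size depended on the choice of peak. Of 13 tested genes of TNF and NF-kB signalling in the authors' deposited table, 11 fell and 2 rose, with the cytokine gene TNF at -1.18, REL, an NF-kB subunit, at -0.91, RIPK1, a kinase of TNF receptor signalling, at -0.84, TNFAIP3, an inhibitor of NF-kB, at -0.55 and TRAF1 at -0.54. Of 23 apoptosis genes in the authors' deposited table, 16 fell and 5 rose, with the death receptor adaptor FADD at -1.04, BIRC2, an inhibitor of apoptosis, at -0.70 and MCL1, a survival protein, at -0.42, while APAF1, the core of the apoptosome, rose by 2.20. Among 18 p53 target genes of the authors' deposited table, 11 fell and 3 rose, and PMAIP1, a pro-apoptotic gene, was at -0.73, GADD45A, a growth arrest gene, at -0.62 and the death receptor gene TNFRSF10B at -0.37, the latter pair each beside a peak that rose. XPC (-0.45 in the authors' deposited table), a sensor of DNA lesions, turned with another choice of peak. Of 17 genes of the unfolded protein and integrated stress response in the authors' deposited table, 9 fell and 7 rose, with the pseudokinase TRIB3 at -0.93, the chaperone genes DNAJB9 at -0.83 and HSPA5 at -0.28, and ATF4, the main transcription factor of this response, at 1.36.

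In the DNA damage response more genes rose than fell, beyond expression-matched but not enrichment-matched random lists. By the authors' deposited table, 8 of 14 rose and 5 fell, among them TOPBP1, an activator of the ATR kinase, at 1.40 and TOP2A, a DNA topoisomerase, at 0.90, against -1.29 for the histone gene H2AX. Those that rose include ATR, whose peak carried another gene's exon. They also include BRCA1, which turned to -0.083 with the mean of its peaks. TP53BP1, a break repair protein, was at -1.04 in the authors' deposited table, close to 0 as a mean over its peaks. Of 19 cell cycle genes in the authors' deposited table, 9 fell and 7 rose, with MCM5, a subunit of the replicative helicase, at -1.21, the proliferation marker MKI67 at -0.69, the mitotic kinase gene AURKA at -0.67 and E2F3, a cell cycle transcription factor, at -0.66.

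Blood cell regulators were mostly lower, though not beyond expression-matched random lists. Of 21 haematopoietic transcription factors in the authors' deposited table, 15 fell and 3 rose, with MYC at -0.83 next to 2 of its peaks that rose, GATA2, a factor of blood stem cells, at -0.76, SPI1, a myeloid master regulator, at -0.44 and RUNX1T1 at -0.43. RUNX1 (-0.19) and FLI1 (-0.33) of the authors' deposited table turned with another choice of peak. Of 10 myeloid marker genes in the authors' deposited table, 6 fell and 2 rose, with MPO, the granule peroxidase, at -0.69, the stem cell antigen CD34 at -1.06 beside another of its peaks that rose, and CTSG, a granule protease, at 0.84. FCGR1A, an Fc receptor gene, was at -0.71 in the authors' deposited table and turned with another choice of peak. Of 3 tested lymphoid markers, 2 rose in the authors' deposited table, among them CD79A, a subunit of the B cell receptor, at 1.09, and no erythroid or megakaryocytic marker was tested. Of 23 chromatin regulators in the authors' deposited table, 15 fell and 7 rose, with the histone methyltransferase gene KMT2D at -0.57 beside a peak that rose, and CHD4, a remodeller, at 0.96. ARID1A (-0.57) and KDM2B (-0.52), by the authors' deposited table, turned with another choice of peak.

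Most ribosomal protein genes with a tested peak rose, beyond expression-matched but not enrichment-matched random lists. Of 14 in the authors' deposited table, 12 rose and 1 fell, with RPL5 at 1.59, RPL19 at 0.95 and RPS6 at 0.94, while RPL13, the gene that fell, was at -0.48 (chosen after its value was seen). RPS24 was at 0.34 in the authors' deposited table and turned lower with another choice of peak, and pseudogene copies can share reads with genes of this family. Of 6 respiratory chain genes in the authors' deposited table, 4 rose and 2 fell, with NDUFS1, of complex I, at 1.08, ATP5F1B, of the ATP synthase, at 0.57, COX4I1, of complex IV, at 0.29 and UQCRFS1, of complex III, at -0.79.

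Set against random lists of genes in the authors' deposited table matched on input FPKM, 2 of 17 lists had medians outside the central 95%, ribosomal proteins (median 0.71, percentile 99.7) and the DNA damage response (0.48, percentile 97.7). Medians inside, by the authors' deposited table, were those of m6A writers (-0.42, percentile 40.2), m6A readers (0.41, 92.6), HIF pathway regulators (-0.40, 36.8), HIF target genes (-0.41, 42.7), glycolysis (0.37, 87.6), p53 target genes (-0.41, 48.0), apoptosis (-0.55, 15.6) and TNF and NF-kB signalling (-0.59, 6.48). The same held in the authors' deposited table for the cell cycle (-0.45, percentile 21.7), the stress response (-0.28, 67.5), haematopoietic transcription factors (-0.38, 68.8), myeloid markers (-0.69, 19.2), lymphoid markers (1.09, 96.6), chromatin regulators (-0.27, 83.6) and the respiratory chain (0.36, 85.5). The median of HIF pathway regulators in the authors' deposited table came to -0.00275 (percentile 56.95) with the mean of each gene's peaks and to 0.44 (78.6) with the peak of highest absolute fold change. It thus has no settled direction. Medians and means differed in sign for the chromatin regulators of the authors' deposited table, whose mean was 0.19. Adjusted over the list alone, 12 of 18 lists of the authors' deposited table kept the same count of changed genes as over all peaks, and HIF target genes came to 14, p53 target genes to 15, the stress response to 17, haematopoietic transcription factors to 20, chromatin regulators to 23 and ribosomal proteins to 14. A percentile describes these libraries and is no p-value, and 5% of random lists lie outside by construction. Matched on peak enrichment in place of expression, among genes whose peak overlapped the peak list, neither call remained: ribosomal proteins of the authors' deposited table came to percentile 97.0 on the enrichment after the combined treatment and 43.3 on the average of both conditions, and the DNA damage response to 92.0 and 52.98. The average contains the fold change, so matching on it cannot decide the calls. On the enrichment after the combined treatment, ribosomal proteins lay close under the upper limit of 97.5. The DNA damage response of the authors' deposited table also came inside with unmatched lists (97.1), with expressed genes only (97.5) and with the mean over peaks (95.3), the cell cycle fell outside with that mean (-0.54, percentile 0.570), and glycolysis rose outside with the peak of highest absolute fold change (0.90, 99.7).

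**Figure D2:**
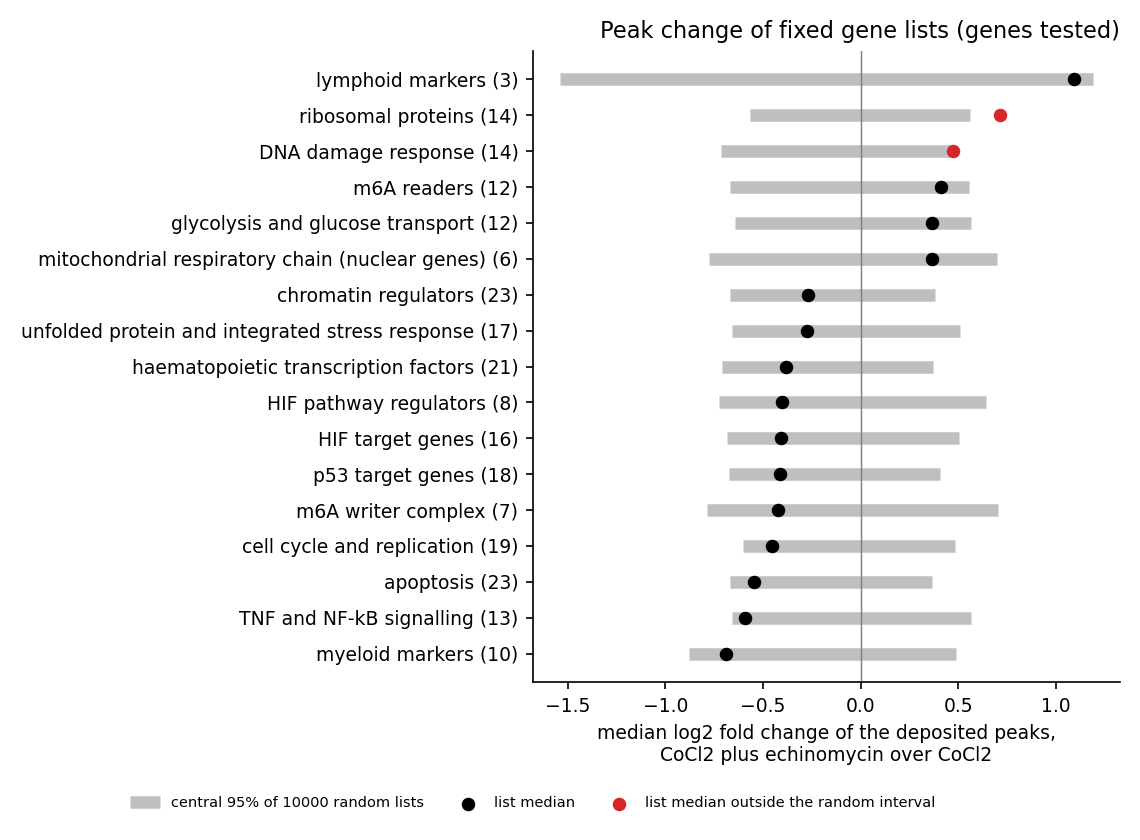
Median log2 fold change of each fixed gene list in the authors' deposited table, CoCl2 plus echinomycin over CoCl2 (points, with genes tested in parentheses), and the central 95% of the medians of 10000 random lists matched on input FPKM (grey bars). Ribosomal proteins, at 0.71, and the DNA damage response, at 0.48, lie to the right of their bars.

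Among changed peaks found in the peak list, weakly enriched ones were more often higher and strongly enriched ones more often lower. Among the changed peaks of the authors' deposited table that overlapped the peak list and whose gene had an FPKM, 62.9% were higher in the weakest quintile of deposited enrichment (exact 95% interval 61.0 to 64.7) and 15.2% in the strongest (13.7 to 16.7). Spearman's rho of fold change with that enrichment was -0.30 across these 12958 changed peaks of the authors' deposited table. Across all matched peaks, changed or not, it was weaker at -0.13. Over changed peaks, fold change also rose with input FPKM (rho 0.30). Genes of higher peaks had a median input of 8.73 FPKM and genes of lower peaks 4.75 FPKM. Peaks that fell can drop out of the peak list, and 613 lower but 12 higher changed peaks of the authors' deposited table in genes with an FPKM had no overlap. With peaks lacking an overlap ranked weakest, which is the extreme case, 51.0% of the changed peaks at the weak end of the authors' deposited table were higher (49.3 to 52.8). Peaks are not independent replicates. Ranked by the average of both conditions, rho was -0.61 across changed peaks of the authors' deposited table and -0.55 across all, but shuffled fold changes alone gave a median of -0.44 (range -0.45 to -0.43 over 100 shuffles), since that average is built from the fold change.

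**Figure D3:**
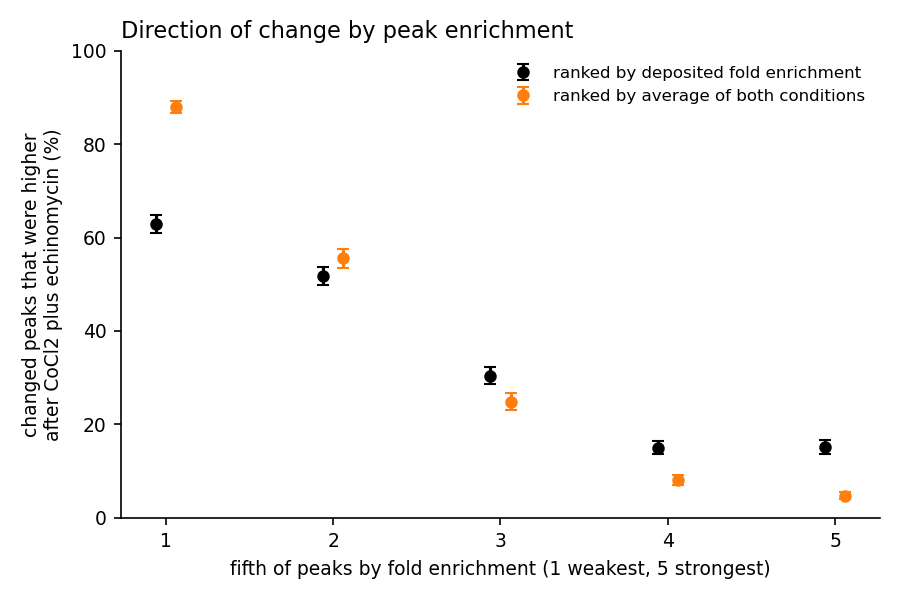
Percentage of changed peaks of the authors' deposited table, in genes with an FPKM, that were higher after CoCl2 plus echinomycin, by quintile of peaks from weakest to strongest fold enrichment, ranked by the deposited enrichment (black) or by the average of both conditions (orange), with exact 95% binomial intervals. On the deposited ranking the share goes from 62.9% in the weakest quintile to 15.2% in the strongest, and peaks without an overlap are not shown.

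In the input RNA of the combined treatment, genes of translation and iron storage had the highest levels. EEF1A1, a translation elongation factor, was at 3381 ± 140.2 FPKM (SD, n = 3), followed by RPS18 at 2204 ± 104.6 FPKM (SD, n = 3) and FTL, the ferritin light chain, at 2181 ± 41.2 FPKM (SD, n = 3). RPS12, RPL41, RPL19, the signal recognition particle RNA gene RN7SL2, EEF1G and AC243919 were also among the highest 10, from 1846 to 1226 FPKM. HIF1A stood at 25.4 ± 0.832 FPKM (SD, n = 3), VEGFA at 12.3 ± 0.617, TNF at 14.5 ± 1.26, MYC at 5.43 ± 0.700, RUNX1 at 4.09 ± 0.0471 and RUNX1T1 at 4.21 ± 0.250. Among m6A genes, YTHDF1 was highest at 47.7 ± 1.58 FPKM (SD, n = 3), ALKBH5 stood at 28.0 ± 1.29 and METTL3 at 6.20 ± 0.352, while METTL14 had 3.39 ± 0.0697, FTO 0.702 ± 0.0373 and IGF2BP1 0.0692 ± 0.00838 FPKM. Myeloid markers were led by MPO at 56.2 ± 2.74 FPKM (SD, n = 3) and KIT, a stem cell factor receptor, at 40.4 ± 1.87. Of the lymphoid markers, CD3D was listed at 32.1 ± 2.30 FPKM (SD, n = 3) while its complex partner CD3E was at 0.181 ± 0.0737, and of erythroid and megakaryocytic markers only ITGA2B passed 1 FPKM, at 1.48 ± 0.195.

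Of 32917 genes in the FPKM table, 12612 had a mean of 1 FPKM or more and 2837 were listed at 0 in all 3 inputs. Pearson's r across the expressed genes, on log2(FPKM + 1), was 0.986, 0.987 and 0.988 between the 3 input libraries, and the median coefficient of variation was 6.06%. Genes are not independent replicates, and no expression comparison with CoCl2 alone was made here. At 5 FPKM the count of expressed genes was 6579.

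**Figure D4:**
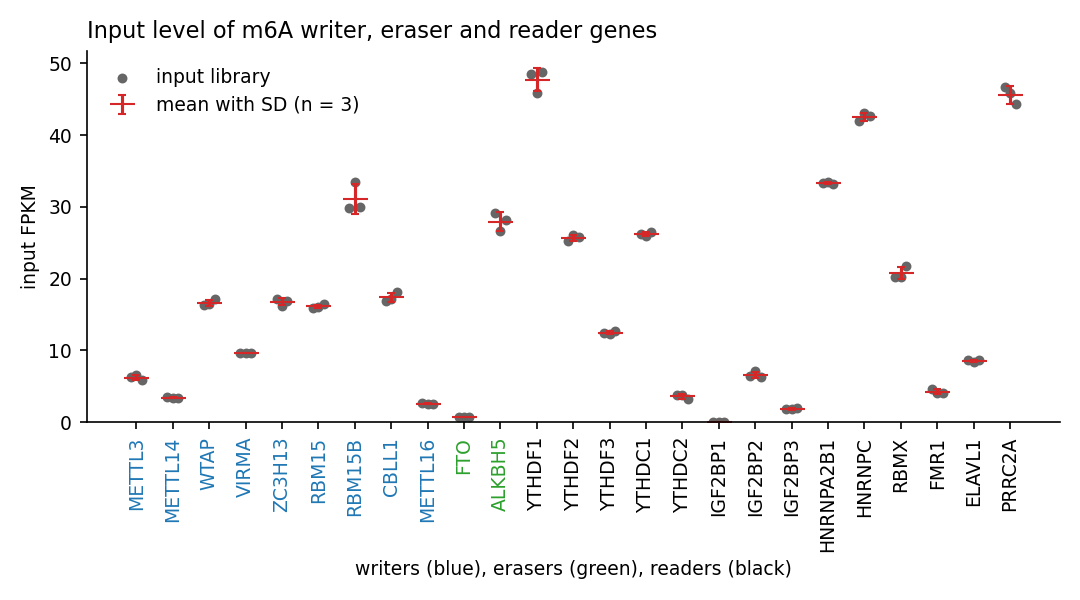
Input FPKM of m6A writer (blue labels), eraser (green labels) and reader (black labels) genes in the 3 input libraries after CoCl2 plus echinomycin (grey points), with the mean and SD (n = 3, red). YTHDF1, at 47.7 FPKM, is the highest and IGF2BP1, at 0.0692 FPKM, the lowest.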

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

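The settings that match random lists on enrichment, require an FDR under 0.05 in the peak list, or leave out exon peaks carrying another gene's exon were chosen after the results were seen. No paired analysis was possible because the peak lists carry no replicate values and FPKM columns of a single group, the inputs, were used, so the planned IP against input comparison, with its replicate block, was not run. Matching on transcript length, the motif search and the comparison with expression change were not run either. Lower peaks outnumbered higher ones under each setting tried for the authors' deposited table: 67.8% were lower at FDR under 0.01, 65.1% of 3434 with a 2-fold limit, 63.1% in expressed genes, 70.0% of 8516 changed genes in place of peaks, 64.9% of those overlapping the peak list by 1 base, 63.8% by at least 50% of their length, 65.7% at an authors' p under 0.05 and 66.4% without exon peaks carrying another gene's exon. The peak list shrank to 23791 peaks at a fold enrichment of 4 or more and to 27921 in expressed genes, since each filter removes peaks. At 5 FPKM 6579 genes counted as expressed, and leaving out each replicate in turn gave 12509 to 12669. Of gene lists apart in the authors' deposited table, 1 remained with unmatched lists, 1 with expressed genes, 0 matched on average enrichment and 0 matched on the enrichment after the combined treatment, while 3 were apart with the peak of highest absolute fold change. Lists apart by their share of genes with a peak numbered 3 at 5 FPKM and 7 to 8 with a replicate left out.

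The choice among a gene's peaks turned the sign of single genes in the authors' deposited table, because a gene's peaks differed in sign: of 232 named or listed genes, 24 reversed, 59 moved by more than 1.5 times and 149 stayed within that with the mean of the gene's peaks, and 27 reversed, 6 lost the call and 199 kept it with the peak of highest absolute fold change. With the mean, the reversed log2 values of the authors' deposited table were TP53BP1 0.037, BRCA1 -0.083, CITED2 0.0165, VHL 0.18, KDM3A 0.98, TRADD 0.22, BID 0.26, CDK6 -0.23, KDM2B 0.74, SLC2A3 0.13, HK2 0.015, PFKFB3 1.01, SLC16A3 -0.0104, FLI1 0.03, RUNX1 0.36, LYL1 0.16, YTHDF2 0.10, RBMX -0.20, ZC3H13 -0.049, METTL16 0.15, FCGR1A 1.13, XPC 0.56, RPS24 -0.53 and ATF6 0.11. With the peak of highest absolute fold change, those of the authors' deposited table were CTU2 3.64, CITED2 0.44, VHL 0.89, EP300 0.98, KDM3A 2.97, RELA 0.62, BCL2L1 2.10, TRADD 1.13, BID 0.83, CASP10 0.63, CDK6 -0.71, ARID1A 0.96, KDM2B 2.33, KMT2C 0.48, SLC2A3 0.68, HK2 0.58, PFKFB3 2.68, PFKP 0.85, FLI1 0.39, RUNX1 0.96, LYL1 0.57, RBMX -0.73, METTL16 1.18, FCGR1A 2.15, XPC 1.71, RPS24 -1.69 and ATF6 0.47. At FDR under 0.01, 215 of the 232 genes remained changed and 17 did not, and a 2-fold limit removed 173. The unknown depth sets no limit that could be computed.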

Other observations

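All term tests, the zinc finger gene count, and the tests within quintiles of expression and within the 3' UTR on deposited enrichment, of peaks missing from the peak list, of background RNA over all peaks and of changes of 4-fold or more were chosen after the results were seen. Genes of RNA splicing and protein turnover were over-represented among genes with a higher peak, though the proteasome was not beyond enrichment-matched random lists. In the authors' deposited table, 60 of 97 tested spliceosome genes rose (61.9% against 29.3% of annotated genes; Fisher's exact test, one-sided, adjusted p = 3.32e-09 over 221 KEGG terms), among them HNRNPU, an RNA-binding protein, at 0.63, SYF2 at 0.82, SNRPD3, a core snRNP protein, at 0.73 and DHX38, a splicing helicase, at 0.89. Other spliceosome genes of the authors' deposited table fell, such as DDX42 at -0.67 and DDX23 at -0.96. Of 29 proteasome genes, 19 rose in the authors' deposited table (exact test, adjusted p = 0.00237), with PSME3, an activator subunit, at 1.18, PSMD11 at 0.98, and the ATPase genes PSMC1 at 0.72 and PSMC4 at 0.70. Ribosome genes (39 of 66, adjusted p = 2.61e-05) and oxidative phosphorylation genes (29 of 49, adjusted p = 0.000616) also rose by the exact test on the authors' deposited table. In all, 15 of 221 KEGG terms passed for higher peaks and 2 for lower peaks, and of 1234 GO terms 159 passed for higher and 5 for lower peaks. The leading GO terms on the authors' deposited table were RNA binding, with 437 of 999 genes higher (43.7% against 25.6% of annotated genes; exact test, adjusted p = 4.98e-37), and nucleic acid binding, with 643 of 922 lower (adjusted p = 1.37e-19). Most RNA binding genes were not higher, since their median in the authors' deposited table was -0.18, at percentile 100 matched on input FPKM or on enrichment after the combined treatment and 33.3 matched on average enrichment. By percentile among random lists of genes in the authors' deposited table, the spliceosome lay at 100.0 matched on input FPKM, 98.3 matched on enrichment after the combined treatment and 27.0 matched on the average enrichment, which contains the fold change, the proteasome at 99.1, 84.1 and 19.3, the ribosome at 99.95, 96.5 and 16.6, and oxidative phosphorylation at 99.8, 92.9 and 22.4.

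Zinc finger genes were over-represented among genes with a lower peak. The KEGG term for herpes simplex virus infection, of which 64.6% of tested genes have symbols starting with ZNF, had 265 of 333 genes lower in the authors' deposited table (exact test, adjusted p = 1.09e-25). Of 377 ZNF genes in the authors' deposited table, many of them encoding DNA-binding repressors, 331 fell, 16 rose and 30 did not pass, so that 87.8% were lower against 53.1% of all genes, with ZNF317 at -1.02 and ZNF160 at -0.76. Their median in the authors' deposited table was -0.73, below each of 10000 random lists matched on input FPKM, of which the lowest had -0.67. The same held for 366 of them matched on enrichment after the combined treatment (median -0.72, lowest random list -0.64) and on average enrichment (median -0.723, lowest random list -0.717). ZNF genes are paralogs whose reads can be shared, and genes are not independent in these tests. TGF-beta signalling passed as well, with 39 of 49 genes lower (exact test, adjusted p = 0.00572 on the authors' deposited table), but its median lay inside the random lists at percentile 14.1.

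Among changed peaks strong ones tended to be lower and weak ones higher, and with peaks missing from the peak list ranked weakest rho of fold change with deposited enrichment was -0.172, which argues against loss of fallen peaks from the list as the whole cause there, while over all peaks it was 0.0645 and that loss could account for the trend. Position in the transcript alone is argued against in 3' UTRs, where rho of changed peaks was -0.323 (-0.214 with missing peaks ranked weakest), and in 5' UTRs (-0.281 and -0.210), while in other exons it went from -0.281 to -0.058, so no trend is held there. Within the upper 3 quintiles of input FPKM the trend held, with rho of changed peaks at -0.306 or below (-0.185 with missing peaks ranked weakest). The split into upper and lower quintiles was made after these values were seen and follows them. Expression also still varies within a quintile, in the highest from 13.9 to 3381 FPKM. The split therefore cannot decide whether expression level accounts for the trend. In the lower 2 quintiles rho was 0.0349 and -0.0453 (0.219 and 0.0660 with missing peaks ranked weakest). No trend is held there, and expression is not argued against. On the average of both conditions, the tests set beforehand gave -0.490 at the highest within quintiles of expression and -0.566 within the 3' UTR, with the later test over all matched peaks at -0.550, but these 3 are void, because shuffled fold changes gave a median of -0.441 on that axis. A larger share of background RNA in the IP libraries of the combined treatment may weaken all strong peaks, and it cannot be told apart from an effect of echinomycin on methylation, which was not tested, because the treatment and its IP libraries are confounded.

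Background RNA alone might be excluded by strong peaks that rose. Of changed peaks in the strongest quintile of average enrichment, 4.71% were higher (exact 95% interval 3.94 to 5.57). The FDR applies to all called peaks together and sets no limit for this share, so it cannot decide whether these rises are real. Of changed peaks in the strongest quintile by deposited enrichment, 15.2% (13.7 to 16.7) were higher. The shuffled values show that the average favours peaks that fell, and the deposited value, measured after the treatment, can favour peaks that rose, so this stays open.

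Changes of 4-fold or more may come largely from few reads in weakly expressed genes. Such changes made up 28.5% of peaks in genes under 1 FPKM and 2.60% in genes of 5 FPKM or more in the authors' deposited table, a ratio of 11.0. Of 1891 such peaks in the authors' deposited table, 551 passed the FDR, and 128 of the changed ones lay in genes of 5 FPKM or more, where few reads are a less direct explanation. No biological explanation was tested for this pattern.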
